A study of Mus musculus with 6 samples.

How the data were processed

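RNA of sorted Flk1+ mouse cells from day 4 embryoid bodies was measured on 6 Affymetrix mouse genome arrays, in 3 groups of 2. Per the labels' protocols, ES cells spent 2 days in a pre-differentiation medium, 100000 cells per well were then plated for embryoid body formation, and cells were sorted by antibody staining for Flk1 and human CD4. Groups and replicate numbers were taken from the sample titles, and the gate of the SclKO cells from the sorting protocol.

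The authors used RMA, affy and limma, per the submitters' processing notes, which give no versions; RMA corrects background, quantile-normalises probes and combines the probes of a probe set. The deposited values are not on a log scale, and their unit is not stated. Their lowest value was 3.256 and their highest 2822995. Between 1040 and 1153 probe sets per array lay above 65535, the ceiling of a 16-bit scanner, which argues against linear intensities. The natural log of the deposited values ran from 1.18 to 14.85, a range that RMA gives in log2, as if e had been raised to the RMA value. The bacterial spike-in controls did not settle the base: their slope against the nominal steps was 0.659 if the natural log is read as log2 and 0.95 if the deposited values are read as linear. All differences are therefore natural-log differences of the deposited values, and reading them the other way changes every one by the same factor of 1.44, with no effect on tests. The design fixed before the data were examined had assumed log2 values; the test was kept and the natural log was taken first. No other column of per-sample values was present, the number of columns left unused being 0.

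The deposited table held 45101 probe sets, of which 64 were controls. A table of the platform's annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211. Symbols were updated through Entrez identifiers for 34754 probe sets and kept for 204. The chromosome of each gene, and the order of genes along chromosome 11, were taken from a RefSeq table of the assembly GRCm38.p6; no coordinates from it are given. For each of 18194 genes, the probe set with the highest mean over the 6 arrays was used. Other probe sets of a gene could differ in size, so each difference holds for the probe set used. A gene was tested if its value exceeded its array's 40th percentile on at least 2 of the 6 arrays, which left 12923 genes. For arrays no read depth exists, and their number limits the precision.

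A mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, so that the 3 groups shared 1 estimate of the spread (residual degrees of freedom 3, prior degrees of freedom 3.15). Tests were two-sided with eBayes, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with calls at an adjusted p under 0.05. Of 21 gene lists fixed before the data were examined, 20 had at least 5 tested members and entered camera with a preset correlation of 0.01, adjusted over 60 tests of lists and comparisons. Of these, 18 passed, 0 passed with an estimated correlation (lowest adjusted p = 0.47), 0 passed fry's directional test, and 18 passed fry's test for change in either direction. Tal1 and Kdr were kept out of every list. Counts adjusted over the list alone are given beside those over all genes.

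The rule for named genes took Tal1, Kdr, the 8 largest rises and falls among called genes whose groups do not overlap, and the largest called members of each list. Since 1 gene was called, a second rule was chosen after the data were seen: the 5 members of each list with the largest difference among those passing over the list alone, and the 8 largest rises and falls per comparison at an unadjusted p under 0.01 without overlap. Members with smaller differences are given as counts, and Etv2, Bcl11a and Kcnq1ot1 were also named after their values were seen. A gene with all arrays of both groups under the limit for dim genes was not named for that comparison.

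The fit was tested on simulated data in which 200 of 12923 genes were shifted in WT Scl+. For WT Scl+ against WT Scl-, 53.7% of genes shifted by 1 log unit were recovered, 97.5% at 2 and 100% at 4; for SclKO against WT Scl+ the shares were 54.6%, 97.9% and 100%. The simulation drew each gene with its own moderated spread, for genes picked at random and independent of each other. The median residual SD was 0.19 log units over all genes tested, but 0.63 for the blood and endothelial transcription factors and 0.69 for the endothelial markers. A list of 20 genes shifted by 1 log unit was called in 20 of 20 simulations with the preset correlation and in 19 with an estimated one. Its members were drawn independently. In the data the estimated correlation was 0.81 for the endothelial markers, 0.59 for the streak genes and 0.37 for the blood and endothelial transcription factors. The simulation therefore cannot say whether the preset correlation suits these lists.

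Alternatives were the replicate number as a block, other filters on dim genes, the mean of all probe sets, probe sets open to cross-matching left out, quantile normalisation, median centring, trended and robust eBayes, only the 2 groups compared, a minimum difference, and each array left out. Array weights and an unadjusted threshold for the overlap were added after the data were seen. Figures were drawn with matplotlib 3.10.9.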

Results

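Gene expression was measured in mouse embryonic stem (ES) cells that had been differentiated into embryoid bodies, 3-dimensional aggregates in which early germ layers form. On day 4, mesodermal cells carrying the surface receptor Flk1 (gene Kdr) were sorted, and total RNA was hybridised to 6 Affymetrix arrays. Scl (gene Tal1) is a basic helix-loop-helix transcription factor needed for blood formation. In the reporter line, derived from the R1 ES line, a human CD4 sequence inserted at the Scl locus reports Scl expression on the cell surface. Flk1+ cells of that line were split by human CD4 into WT Scl+ (n = 2 arrays) and WT Scl- (n = 2). The third group, SclKO (n = 2), was Flk1+ cells of a line without functional Scl that was derived from the J1 ES line, and by the sorting protocol it was collected on Flk1 alone, although the sample titles call these cells Scl negative. Knockout, ES line and sort gate therefore cannot be told apart in either comparison with SclKO. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays.

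The median deposited value per array lay between 180.6 and 190.5, and the natural log of the values had a median between 5.2 and 5.25. Values are given as natural logs, and differences as log units. The base in which the values were raised is not stated: 1 log unit is 2.72-fold in the deposited values, or 2-fold if their natural log is an RMA log2 value. Folds are given under both readings, the 2-fold reading first. Values above 65535, the ceiling of a 16-bit scanner, on every array argue against reading the deposited values as linear, which gives the larger, second folds. Values under their array's limit for dim genes (its 40th percentile, 4.54 to 4.59) give no exact level, so differences that rest on them are as measured. A size "at the limit" sets such values to the limit and is a lower bound for the probe set used, not for every probe set of the gene. It is given where both arrays of a group lay under the limit and for every fold that uses such a value. WT Scl+ replicate 1 correlated less with WT Scl+ replicate 2 (Pearson r = 0.9687 across genes, which are not independent replicates) than with any other array (r = 0.9745 and 0.9866 for the WT Scl- arrays, 0.9738 and 0.9757 for the SclKO arrays). The first principal component held 55.9% of the variance, with WT Scl+ replicate 2 at -51.3 and the other arrays between -9.9 and 26. That array also had the highest mean of the bacterial control bioB (11.11, against 10.2 to 10.69 on the others), the lowest upper quartile (7.18, against 7.28 to 7.34) and the lowest actin 3' minus 5' difference (-0.2, against -0.1 to -0.02), while its Gapdh 3' minus 5' difference (1.22) lay within the range of the others (1.11 to 1.24). Whether these technical values bear on its expression was not tested.

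Tal1, the targeted gene, was highest in WT Scl+ and lowest in SclKO. Its level was 8.65 and 8.78 on the WT Scl+ arrays, 6.52 and 7.97 on the WT Scl- arrays, and 5.71 and 6.14 on the SclKO arrays. SclKO was lower than WT Scl+ by 6.91-fold or 16.2-fold (difference -2.79 log units, SE 0.45, limma adjusted p = 0.131). The difference between WT Scl+ and WT Scl- was 1.47 log units (SE 0.45, limma adjusted p = 0.442), and WT Scl- replicate 2 lay much nearer to WT Scl+ than replicate 1 did (0.74 log units without replicate 1). Which part of the transcript the probe set reads, relative to the knockout, is not given in the sources used here. Kdr, the sort marker, was at 11.1 ± 0.34 in WT Scl+, 11.18 ± 0.06 in WT Scl- and 11 ± 0.24 in SclKO (mean ± SD, n = 2 each), and no difference between groups exceeded 0.18 log units.

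**Figure D1:**
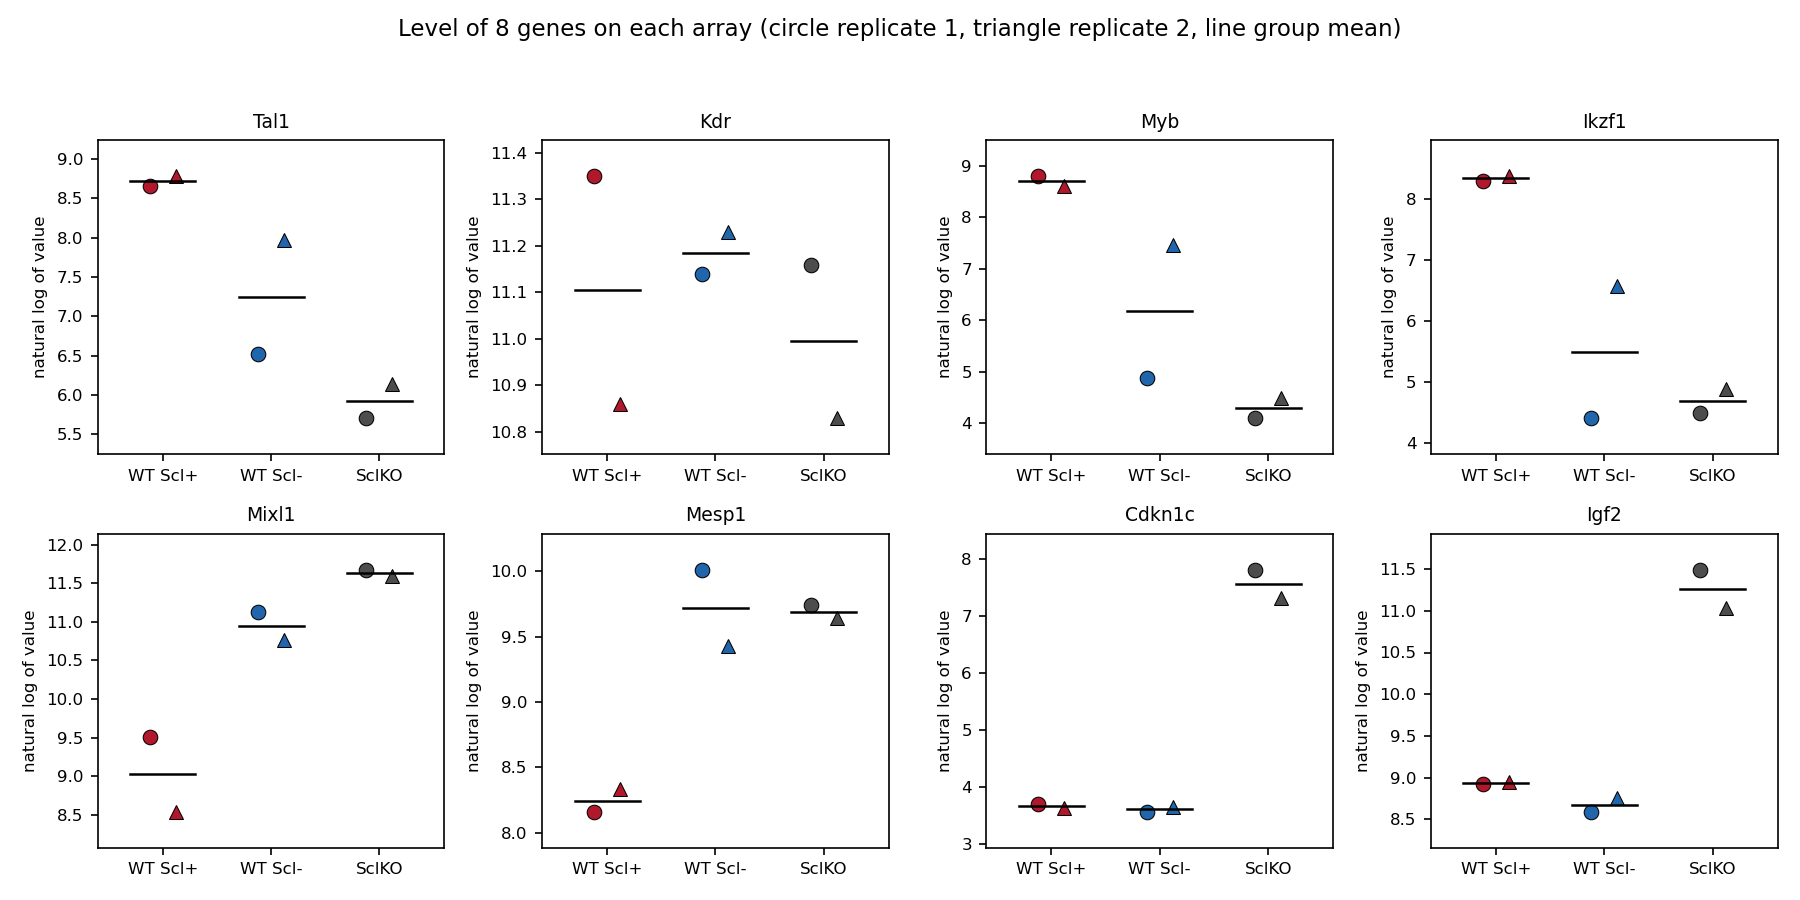
Natural log of the deposited value (vertical axis, a separate scale in each panel) of Tal1, Kdr, Myb, Ikzf1, Mixl1, Mesp1, Cdkn1c and Igf2 on the 6 arrays, by group; circles are replicate 1, triangles replicate 2 and lines group means. Tal1 was at 8.65 and 8.78 in WT Scl+ and at 5.71 and 6.14 in SclKO, and Cdkn1c was at 7.8 and 7.31 in SclKO against 3.56 to 3.69 on the WT arrays.

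The first comparison, WT Scl+ against WT Scl-, asks which genes mark Flk1+ mesoderm that has switched on Scl. Blood and endothelial genes were higher in the WT Scl+ cells, and genes of the primitive streak and some cardiac transcription factors were lower, as measured by lists. None of these lists passed with an estimated correlation (adjusted p = 0.47), 0 genes passed over all genes tested, and 0 of the 21 endothelial markers passed over the list alone. Of the 26 transcription factors of blood and endothelium, 23 had a positive difference, and the median was 1.7 log units. All 21 endothelial markers tested had a positive difference, with a median of 1.51 log units. Of the 16 primitive streak and early mesoderm genes tested, 14 had a negative difference, with a median of -1 log unit.

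Over the list alone, 17 of the 26 blood and endothelial transcription factors passed the test as higher in WT Scl+ and 0 as lower; over all genes tested none passed. Ikzf1, a regulator of lymphoid and early blood cells, was higher by 2.85 log units (SE 0.64, 7.22-fold or 17.3-fold, at the limit at least 6.82-fold or 16-fold). Another Ikzf1 probe set, also above the limit for dim genes, gave 1.14 log units, so that bound holds for the probe set used. Sox18, an endothelial factor, was higher by 2.74 log units (SE 0.98) and Cbfa2t3, a corepressor found in Scl complexes, by 2.67 (SE 0.73). The other Cbfa2t3 probe sets gave 0.64, 1.25 and 0.34 log units. The ETS factors Fli1 and Erg were higher by 2.61 (SE 0.82) and 2.57 log units (SE 0.84). Adjusted over the list alone, p was 0.0268 for Ikzf1, 0.0466 for Sox18, 0.0367 for Cbfa2t3, 0.0397 for Fli1 and 0.0404 for Erg. The differences of these 5 genes were 1.77, 1.47, 1.67, 1.29 and 1.22 log units without WT Scl- replicate 1, and without replicate 2 those of Fli1 and Erg were 3.93 and 3.92. As a group these factors were higher than other genes (camera, preset correlation, adjusted p = 1.12e-12; adjusted p = 0.47 with an estimated correlation). The mean level of the list was 7.88 and 7.9 on the WT Scl+ arrays, but 5.84 and 7.06 on the WT Scl- arrays. The median difference was 1.04 log units for these factors and 0.78 for the endothelial markers without WT Scl- replicate 1. The endothelial markers were higher as a group (adjusted p = 2.49e-12; 0.47 as adjusted p with an estimated correlation), while 0 of the 21 passed over the list alone. Tie1, an endothelial receptor kinase, differed by 1.32 log units (SE 0.32), Egfl7 by 0.81 (SE 0.27; 0.44 without WT Scl- replicate 1) and Mmrn2 by 0.78 (SE 0.25). On this list, too, WT Scl- replicate 2 lay between the groups, at 6.54 against 5.08 for replicate 1 and 6.93 and 7.62 for WT Scl+.

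Genes of differentiating blood cells were also higher in WT Scl+ as lists, but not in every member. The difference was positive for 8 of 10 erythroid, 8 of 10 megakaryocyte and 10 of 13 macrophage genes tested, the last with a median of 0.29 log units. Lower in WT Scl+ without overlap of the arrays were 2 megakaryocyte and 3 macrophage genes. Of 10 erythroid and globin genes tested, 4 passed over the list alone, and the group passed at an adjusted p = 6.39e-05 (adjusted p = 0.47 with an estimated correlation). The embryonic globin genes Hbb-bh1 and Hba-x were higher by 2.67 (SE 0.54) and 1.55 log units (SE 0.23; at the limit 0.87). The glycophorin gene Gypc was higher by 1.26 (SE 0.26), and Alas2, the erythroid enzyme that starts haem synthesis, by 0.8 log units (SE 0.17). Of 10 megakaryocyte and early blood surface genes, 5 passed over the list alone, with a group adjusted p = 0.000704 (adjusted p = 0.47 with an estimated correlation). They were Alox5ap (1.64 log units, SE 0.28, at the limit 1.26), F2r (1.42, SE 0.46, and 0.71 without WT Scl- replicate 1), Kit (1.17, SE 0.31), Itga2b (1.12, SE 0.35) and Plek (0.89, SE 0.2). Of 13 macrophage and leukocyte markers, Mpo (2.23 log units, SE 0.54, and 1.47 without WT Scl- replicate 1) and Was (1.31, SE 0.3) passed over the list alone, and the group passed at an adjusted p = 0.017 (adjusted p = 0.47 with an estimated correlation). Without WT Scl+ replicate 2 the macrophage group did not pass (adjusted p = 0.351).

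In the opposite direction, 8 of the 16 primitive streak and early mesoderm genes passed as lower over the list alone, with a group adjusted p = 1.47e-07 (adjusted p = 0.47 with an estimated correlation). Eomes and Mixl1, factors of early mesendoderm, differed by -1.97 (SE 0.46) and -1.92 log units (SE 0.33), Lhx1 by -1.75 (SE 0.56), Wnt3 by -1.39 (SE 0.28) and Evx1 by -1.37 (SE 0.42). The list level was 7.24 and 6.3 on the WT Scl+ arrays, so the median difference of this list was -1.62 log units without WT Scl+ replicate 1 and -0.5 without replicate 2. Without replicate 2 Eomes, Lhx1 and Evx1 differed by -1.24, -0.92 and -0.7 log units. Of 16 cardiac transcription factors tested, 5 passed as lower over the list alone. They were Isl1, a factor of the second heart field (-1.81 log units, SE 0.35), Tbx2 (-1.53, SE 0.41, and -1.01 without WT Scl- replicate 1), Mesp1, a factor of the earliest cardiac mesoderm (-1.47, SE 0.22), Gata4 (-0.69, SE 0.2) and Gata6 (-0.6, SE 0.17). Other probe sets above the limit for dim genes gave only -0.15 log units for Gata6, but -0.93 for Gata4 and -2.05 for Isl1. The cardiac group passed at an adjusted p = 0.00759 (adjusted p = 0.47 with an estimated correlation), and did not pass without WT Scl+ replicate 2 (adjusted p = 0.0906, median difference -0.15 log units against -0.51 with all arrays). The 19 cardiac contractile genes tested had a median difference of 0.02 log units and a mean of -0.13, and did not pass (adjusted p = 0.66).

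Over all 12923 genes tested, limma called 0 genes higher and 0 lower in WT Scl+ at an adjusted p under 0.05, with a lowest adjusted p of 0.399. At an unadjusted p under 0.05, 698 genes were higher and 483 lower, against 646 in all that chance would give. Among genes chosen by size after their values were seen, Atp2a3, a calcium pump, was higher by 2.79 log units (SE 0.62), and Calcrl, a receptor subunit of endothelial cells, by 2.7 (SE 0.5). Another Atp2a3 probe set gave 0.54 log units. Hoxb5 was higher by 2.27 (SE 0.5), Gask1b by 2.25 (SE 0.58) and Tspan12 by 2.21 (SE 0.42). Those of Atp2a3 and Gask1b were 1.77 and 1.37 log units without WT Scl- replicate 1. The signalling gene Wnt5a was lower in WT Scl+, at 7.87 ± 0.99 against 10.28 ± 0.31 in WT Scl- (mean ± SD, n = 2). Pcsk5 differed by -2.06 log units (SE 0.52), L1cam by -1.92 (SE 0.52), Prdm14 by -1.9 (SE 0.49) and Efnb3 by -1.82 (SE 0.24). The differences of Pcsk5, L1cam and Prdm14 were -1.27, -1.09 and -1.19 without WT Scl+ replicate 2. The groups did not overlap for 37.4% of the genes tested, where chance gives 33.3%. Without WT Scl+ replicate 1, which leaves only the array farthest from the rest in that group, 35 genes were called higher and 168 lower.

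The second comparison, SclKO against WT Scl+, sets all Flk1+ cells of the line without functional Scl beside the reporter-positive part of WT Flk1+ cells. Sort gate and ES line differ here as well as Scl. Blood and endothelial genes, which lay higher in WT Scl+ than in WT Scl-, lay lower in SclKO as lists, and streak genes and some cardiac transcription factors lay higher. None of these lists passed with an estimated correlation (adjusted p = 0.47), and over the list alone 3 of the 21 endothelial markers passed as lower and 2 of the blood and endothelial transcription factors as higher. The 26 blood and endothelial transcription factors had a median difference of -2.05 log units, and the 21 endothelial markers of -1.28, with all 21 negative. All 16 streak and early mesoderm genes had a positive difference, with a median of 1.6 log units. Cdkn1c, an imprinted inhibitor of the cell cycle, was the 1 gene called over all genes tested.

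Of the blood and endothelial transcription factors, 17 passed as lower and 2 as higher over the list alone, with a group adjusted p = 4.5e-12 (adjusted p = 0.47 with an estimated correlation). Cbfa2t3 was lower by 27.2-fold or 118-fold (-4.77 log units, SE 0.73, at the limit at least 21.5-fold or 83.9-fold) and Myb, needed for definitive blood, by 21.4-fold or 83.1-fold (-4.42, SE 0.76, at the limit at least 17.7-fold or 63.1-fold). The other Cbfa2t3 probe sets, also above the limit for dim genes, gave only -0.76, -0.94 and -0.42 log units, so that size holds for the probe set used. Those of Myb gave -3.87 and -4.59. Ikzf1 differed by -3.66 log units (SE 0.64), Sox7 by -3.62 (SE 0.83) and Fli1 by -3.58 (SE 0.82). Other probe sets gave -1.75 log units for Ikzf1, -1.14 for Sox7 and -3.1 for Fli1. Higher in SclKO were Etv2, an early activator of blood and endothelial genes that acts upstream of Scl (1.06 log units, adjusted p = 0.024 over the list alone), and Bcl11a (0.79, adjusted p = 0.00897 over the list alone). Of the endothelial markers, Tie1 (-1.98 log units, SE 0.32, at the limit -1.35), Egfl7 (-1.12, SE 0.27) and Mmrn2 (-1.07, SE 0.25) passed over the list alone, and the group passed at an adjusted p = 5.3e-10 (adjusted p = 0.47 with an estimated correlation). On the SclKO arrays the endothelial list had a mean level of 5.56 and 6.2.

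Of the erythroid and globin genes, 5 of 10 passed as lower over the list alone, with a group adjusted p = 0.000302 (adjusted p = 0.47 with an estimated correlation). Hbb-bh1 differed by -3.54 log units (SE 0.54), Gypc by -1.75 (SE 0.26), Hba-x by -1.28 (SE 0.23, at the limit -0.89), Alas2 by -0.94 (SE 0.17) and Epor, the erythropoietin receptor, by -0.55 (SE 0.15). Of the megakaryocyte and early blood surface genes, 5 of 10 passed as lower, with a group adjusted p = 3.37e-05 (adjusted p = 0.47 with an estimated correlation). Plek differed by -1.88 log units (SE 0.2, at the limit -1.29), Itga2b by -1.77 (SE 0.35), Alox5ap by -1.67 (SE 0.28, at the limit -1.28), F2r by -1.55 (SE 0.46) and Kit by -1.49 (SE 0.31). The median difference of this list was -1.41 log units, and -0.89 without WT Scl+ replicate 2. The macrophage and leukocyte markers did not pass as a group (adjusted p = 0.117), although Mpo (-2.48 log units, SE 0.54), Was (-1.8, SE 0.3) and Cd44 (-0.57, SE 0.16) passed as lower over the list alone and Ctsc (1.22, SE 0.21) as higher. The macrophage group passed as lower without SclKO replicate 2 (adjusted p = 0.0382) and without WT Scl- replicate 1 or 2, which changes only the pooled spread (adjusted p = 0.0382 and 0.0475). Of the genes named for this comparison, Ikzf1, Itga2b, Plek, Mpo, Hba-x and Wnk4, all lower in SclKO, and Bcl11a, Lhx1 and Tbx2, all higher, lie on chromosome 11, whose 1119 tested genes had a median difference of -0.146 log units in this comparison, against 0.034 to 0.085 on each of the other autosomes.

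Of the 16 primitive streak and early mesoderm genes, 12 passed as higher in SclKO over the list alone, with a group adjusted p = 1.24e-10 (adjusted p = 0.47 with an estimated correlation). Gsc, a gene of the organiser, was higher by 2.66 log units (SE 0.4), Mixl1 by 2.61 (SE 0.33), Eomes by 2.39 (SE 0.46), Lefty2 by 2.23 (SE 0.46) and Lhx1 by 2.19 (SE 0.56). Without WT Scl+ replicate 2 the median difference of this list was 1.01 log units, and that of Lhx1 was 1.36. Of the cardiac transcription factors, 5 of 16 passed as higher over the list alone. They were Isl1 (1.7 log units, SE 0.35), Mesp1 (1.45, SE 0.22), Tbx2 (1.42, SE 0.41), Gata6 (1.12, SE 0.17) and Gata4 (0.99, SE 0.2). Other probe sets above the limit for dim genes gave only 0.46 log units for Gata6, but 1.43 for Gata4 and 1.71 for Isl1. The cardiac group passed at an adjusted p = 0.0165 (adjusted p = 0.47 with an estimated correlation), and did not pass without WT Scl+ replicate 2 (adjusted p = 0.143) or without SclKO replicate 1 (adjusted p = 0.0679). Its median difference, 0.39 log units, was 1.01 and 0.11 without WT Scl+ replicate 1 and 2, and 0.23 and 0.67 without SclKO replicate 1 and 2. The cardiac contractile genes did not pass (adjusted p = 0.894, median 0.02 log units).

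**Figure D2:**
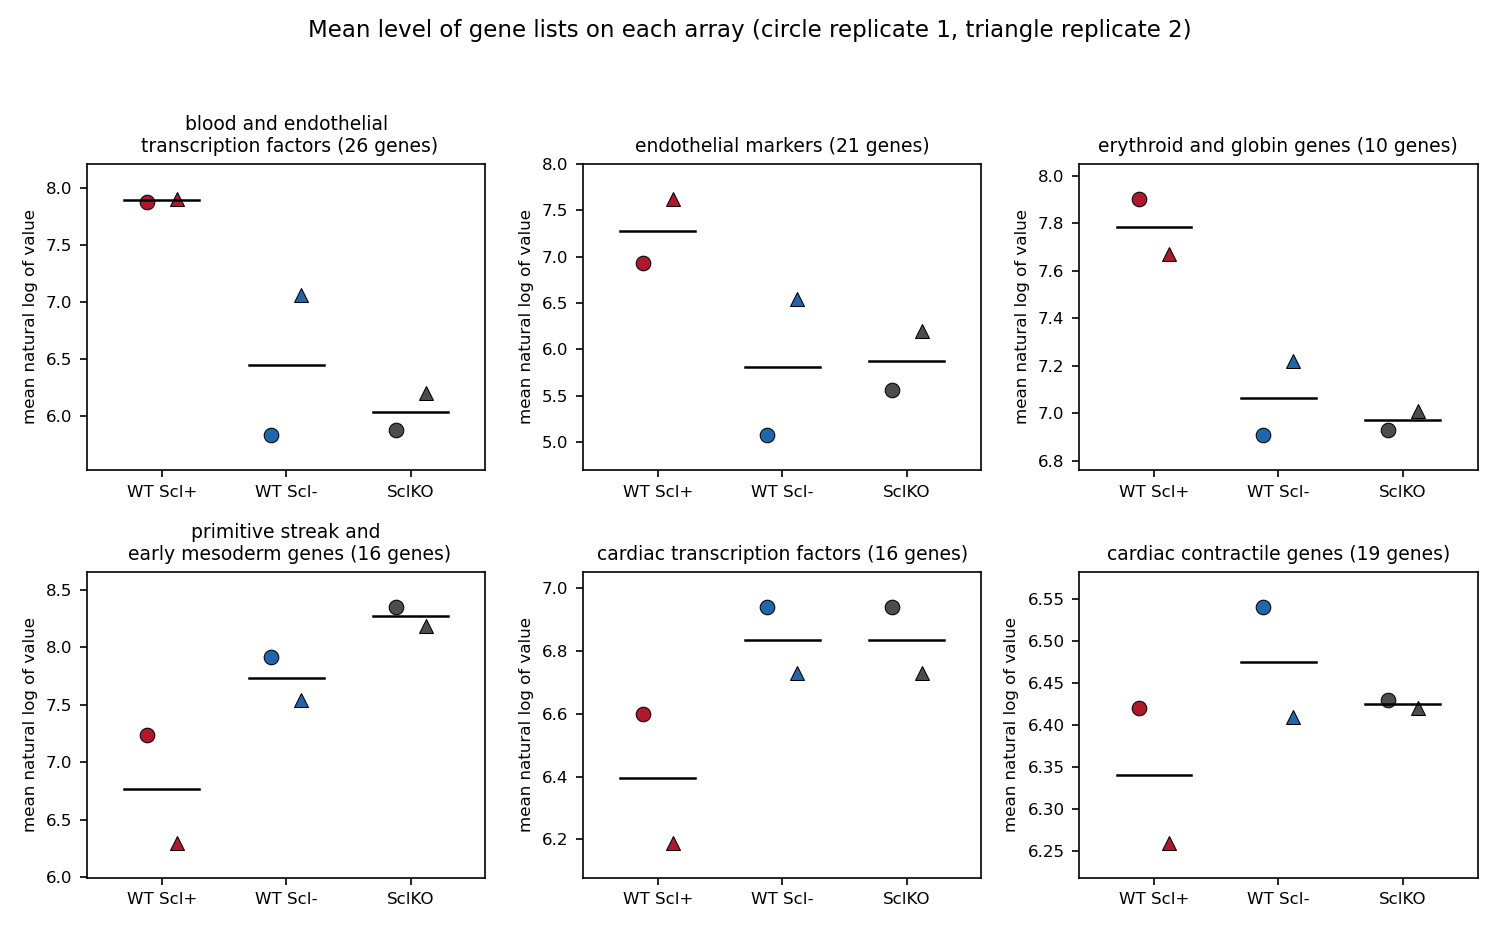
Mean natural log of the deposited values over the tested members of 6 gene lists (vertical axis, a separate scale in each panel) on the 6 arrays, by group; circles are replicate 1, triangles replicate 2 and lines group means. The blood and endothelial transcription factors were at 7.88 and 7.9 in WT Scl+, 5.84 and 7.06 in WT Scl- and 5.88 and 6.2 in SclKO, and the primitive streak genes at 7.24 and 6.3, 7.92 and 7.54, and 8.35 and 8.19.

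Over all 12923 genes, limma called 1 gene higher in SclKO than in WT Scl+ and 0 lower. Cdkn1c was at 7.56 ± 0.34 in SclKO and 3.66 ± 0.05 in WT Scl+ (mean ± SD, n = 2), a difference of 3.9 log units (SE 0.2, 14.9-fold or 49.4-fold, adjusted p = 0.0106). On all WT arrays it lay under the limit for dim genes, and at the limit it was at least 8-fold or 20.1-fold higher. Its call was lost without WT Scl+ replicate 2 (adjusted p = 0.161) and without SclKO replicate 1 or 2 (adjusted p = 0.11 and 0.0593). At an unadjusted p under 0.05, 925 genes were higher and 879 lower, against 646 in all by chance. Among genes chosen by size after their values were seen, Tal2, a relative of Tal1, differed by -4.68 log units (SE 0.83, at the limit -3.9), Wnk4 by -4.14 (SE 0.92) and Tnfaip2 by -3.73 (SE 0.84). Another Tal2 probe set gave -1.34 log units, and others of Tnfaip2 gave -2.12 and -1.05. Frzb, a secreted inhibitor of Wnt signalling, was higher in SclKO by 2.71 log units (SE 0.57), Cdh11 by 2.69 (SE 0.68, and 1.61 without WT Scl+ replicate 2), the imprinted gene Phlda2 by 2.65 (SE 0.37), Tac1 by 2.55 (SE 0.52) and Tgfbi by 2.41 (SE 0.4). The groups did not overlap for 43.4% of the genes, where chance gives 33.3%. Without WT Scl+ replicate 1, 535 genes were called higher and 164 lower, and 44 were called lower when only these 2 groups were fitted.

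The first 2 comparisons share the WT Scl+ arrays and were set side by side to see which genes separate WT Scl+ from both other groups. At the adjusted threshold 0 genes were shared in either direction. At an unadjusted p under 0.05 in both, a threshold chosen after the data were seen, 433 genes were higher in WT Scl+ than in both WT Scl- and SclKO. Independent lists would share 47.5, and 100 simulations of unchanged groups with shared WT Scl+ arrays gave 78.3 on average and 99 at most. In the opposite direction 317 genes were lower in WT Scl+, against 34.6 for independent lists and 79.4 on average (107 at most) in the simulations. Hapln1, Gimap4 and Csgalnact1 were among those higher in WT Scl+, by 3.3 (SE 1.27), 3.02 (SE 1.06) and 2.87 log units (SE 0.97) over WT Scl-. These were 1.23, 1.31 and 1.27 without WT Scl- replicate 1, on which Gimap4 and Csgalnact1 were dim (1.82 and 2.35 at the limit with both arrays), and 5.36, 4.73 and 4.47 without replicate 2. For Gimap4 and Csgalnact1 the differences without replicate 2 rest on dim WT Scl- values alone and give no exact size. Against WT Scl+, the SclKO differences of Hapln1, Gimap4 and Csgalnact1 were -3.65, -3.36 (at the limit -2.34) and -3.45 log units. Wnt5a, Cdh11, Gas1 and Foxf1 were among those lower in WT Scl+, by -2.41, -2.2, -1.93 and -2.04 log units against WT Scl-. Another Foxf1 probe set gave -0.47 log units. Cdh11, Gas1 and Foxf1 differed by -1.12, -0.96 and -1.32 without WT Scl+ replicate 2, and without replicate 1 Gas1 differed by -2.9. The covariance of the differences was 0.156, against 0.0293 in the simulations. Because 2 WT Scl+ arrays cannot be split into 2 sets of 2, part of the excess may come from the shared arrays. The simulated genes were independent of each other, whereas an array such as WT Scl+ replicate 2 can move many genes together. The simulations therefore do not bound the overlap that the shared arrays alone could give.

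The third comparison, SclKO against WT Scl-, sets mesoderm without functional Scl beside WT mesoderm sorted as negative for the human CD4 reporter of Scl. At an unadjusted p under 0.05, 406 genes were higher and 308 lower in SclKO, against 646 in all by chance. Streak and early mesoderm genes were higher in SclKO, with 15 of 16 positive and a median of 0.53 log units, although 0 passed over the list alone and the group did not pass with an estimated correlation (adjusted p = 0.491). Imprinted genes moved both ways, led by Cdkn1c and Igf2 upwards and Meg3 and Rian downwards. The endothelial markers (median 0.02 log units, mean 0.07, adjusted p = 0.894, direction down in the test) and the cardiac transcription factors (median 0.07 log units, mean 0, adjusted p = 0.684) did not pass.

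Cdkn1c was the 1 gene called higher, and 0 were called lower (limma). It was at 3.6 ± 0.06 in WT Scl- (mean ± SD, n = 2), lower than in SclKO by 15.5-fold or 52.2-fold, and at the limit by at least 7.85-fold or 19.5-fold, a difference of 3.95 log units (SE 0.2, adjusted p = 0.00971). The call was lost when any 1 of the 6 arrays was left out, with adjusted p between 0.0509 and 0.223 and a difference between 3.71 and 4.2 log units. Igf2, an imprinted growth factor gene, was higher by 2.59 log units (SE 0.19, adjusted p = 0.0565), and Igf2r, its imprinted receptor gene, by 1.13 (SE 0.24). Meg3 and Rian, maternally expressed non-coding RNAs of one imprinted cluster, differed by -1.5 (SE 0.15) and -1.6 log units (SE 0.24), and Kcnq1ot1 by -0.79. Over the list of 21 imprinted genes tested, these 3 rises and 3 falls passed over the list alone. The list did not pass in 1 direction (adjusted p = 0.676, median -0.06, mean 0.16), whereas fry's test for change in either direction gave an adjusted p = 0.00494. The same 3 rises and the falls of Meg3 and Rian also passed over the list alone against WT Scl+.

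The streak and early mesoderm genes passed as a group (adjusted p = 0.000179; adjusted p = 0.491 with an estimated correlation), with 0 members passing over the list alone. Gsc was higher by 1.35 log units (SE 0.4) and Lefty2 by 1.03 (SE 0.46; 0.64 without WT Scl- replicate 2). Endoderm markers passed as higher in SclKO (median 0.31 log units, adjusted p = 0.00731; adjusted p = 0.47 with an estimated correlation), and 1 of 14 passed over the list alone. That member was Spink1, a secreted protease inhibitor, higher by 2.14 log units (SE 0.4). The list level was 6.78 and 6.81 in SclKO, 6.26 and 6.24 in WT Scl-, and 7 and 6.43 in WT Scl+. The blood and endothelial transcription factors passed as lower in SclKO (median -0.39 log units, adjusted p = 0.0292; adjusted p = 0.678 with an estimated correlation), with 0 members passing over the list alone. Without WT Scl- replicate 2, the array with the higher Tal1, these factors lay in the opposite direction and did not pass (adjusted p = 0.223), and the endothelial markers passed as higher in SclKO (adjusted p = 1.66e-07). The endothelial markers passed as lower without WT Scl- replicate 1 (adjusted p = 1.01e-06) and without SclKO replicate 2 (adjusted p = 0.0327). The factors also did not pass without SclKO replicate 1 (adjusted p = 0.292) or without either WT Scl+ array (adjusted p = 0.0716 for each). Their median difference was -0.98 and 0.26 log units without WT Scl- replicate 1 and 2, and -0.25 without SclKO replicate 1.

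The megakaryocyte and early blood surface genes passed as lower (adjusted p = 0.0197; adjusted p = 0.47 with an estimated correlation), with Plek alone passing over the list (-0.99 log units, SE 0.2, at the limit -0.39, adjusted p = 0.0229 over the list alone). Plek lies on chromosome 11, whose tested genes had a median of -0.154 log units in this comparison. Hypoxia and glycolysis genes passed as lower (median -0.11 log units, adjusted p = 0.0122; adjusted p = 0.47 with an estimated correlation), with 0 members passing over the list alone. Neither group passed without WT Scl- replicate 2 (adjusted p = 0.361 and 0.223) or without SclKO replicate 1 (adjusted p = 0.32 and 0.188). With all arrays kept, the megakaryocyte group did not pass with the mean of all probe sets of a gene (adjusted p = 0.116) or without a filter on dim genes (adjusted p = 0.477). Its median difference, -0.16 log units, was -0.39 and -0.07 without WT Scl- replicate 1 and 2, and -0.09 and -0.36 without SclKO replicate 1 and 2, while that of the hypoxia genes was -0.02 without WT Scl- replicate 2. Among genes chosen by size after their values were seen, Cyp4x1 was higher in SclKO by 3 log units as measured (SE 0.44), but by 0.85 at the limit, Tac1 by 2.38 (SE 0.52), Col4a6 by 1.9 (SE 0.45, at the limit 1.08), Tgfbi by 1.89 (SE 0.4) and Spsb4 by 1.8 (SE 0.3). Mfap3l differed by -2.17 log units (SE 0.37, at the limit -1.24), Gm6958 by -1.68 (SE 0.23), Morc4 by -1.38 (SE 0.36, and -0.81 without SclKO replicate 2), Lgr5 by -1.33 (SE 0.34, and -0.8 without WT Scl- replicate 2) and B4galnt2, on chromosome 11, by -1.31 (SE 0.27). Other B4galnt2 probe sets above the limit for dim genes gave -0.97 and -0.18 log units.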

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

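The search over probe sets outside the gene table was made after the results for genes were seen. Of 28401 probe sets that passed the filter, 15478 were not used in the gene table. With limma over all 28401, probe set 1426936_at, a second one of the gene Gm6958, was lower in SclKO than in WT Scl+ by -4.12 log units (SE 0.16, adjusted p = 0.00289) and than in WT Scl- by -3.98 (SE 0.16, adjusted p = 0.00356). Its level was 7.28 and 7.11 on the SclKO arrays and 11.1 to 11.38 on the WT arrays. The probe set that stands for Gm6958 in the gene table differed by -1.68 log units from WT Scl- (SE 0.23), so the 2 probe sets of this predicted gene gave the same direction and different sizes. Probe set 1456319_at, which has no gene name in the table used here, was lower in SclKO by -4.77 log units against WT Scl+ (SE 0.17, adjusted p = 0.00266) and by -4.59 against WT Scl- (SE 0.17, adjusted p = 0.00336). Its level was 4.37 and 4.64 in SclKO and 9.04 to 9.3 on the WT arrays. Both signals stood out because they lie in data that the comparisons of genes do not use. No explanation, technical or biological, was tested for them.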

How the results depend on the processing

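Single genes were followed under some of the settings only. Cdkn1c kept its direction against both WT groups with the replicate block, the mean of all probe sets, quantile normalisation and trended and robust eBayes. It also did so with only the 2 groups fitted and with each array left out. Its call against WT Scl- was lost when only the 2 groups were fitted (adjusted p = 0.0509; 0.00375 to 0.0509 over the settings that keep all arrays of both groups), where the count of genes higher was 0. Of the genes called higher in SclKO than in WT Scl+ (1 as reported), there were 2 with the replicate block, 5 with the 60th percentile filter, 3 with the mean of all probe sets, 3 without probe sets ending in _x_at or _s_at, 8 with trended and robust eBayes, and 5 with only the 2 groups. Of those called lower (0 as reported), there were, in the same order, 1, 4, 1, 2, 11 and 44. Against WT Scl-, the count of higher genes was 2 with the 60th percentile filter, the mean of all probe sets, the left-out probe sets, trended eBayes and array weights, a setting chosen after seeing the data. The count of lower genes there was 2 with the mean of all probe sets, 1 without the left-out probe sets and 1 with trended eBayes. The cause was not tested; the 60th percentile filter, the mean of all probe sets and the left-out probe sets also tested fewer genes (9680, 12008 and 12616 against 12923). The overlap of the first 2 comparisons, 0 and 0 as reported, was 433 and 317 at an unadjusted p. Lists past the threshold, 7, 6 and 5 as reported, numbered 0 in each comparison with an estimated correlation and 0 with fry, and 12 for WT Scl+ against WT Scl- with the mean of all probe sets.

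Leaving out 1 array at a time, with the lone array assumed to vary like the others, gave 0 to 35 genes higher and 0 to 168 lower in WT Scl+ than in WT Scl-. The ranges were 0 to 535 higher and 0 to 164 lower for SclKO against WT Scl+, 0 to 0 in both directions against WT Scl-, and 0 to 29 and 0 to 157 for the overlap. Every highest value above 0 came without WT Scl+ replicate 1. Lists past the threshold ranged over 7 to 11, 5 to 8 and 2 to 8. Without WT Scl- replicate 2, the blood and endothelial transcription factors (adjusted p = 0.223; 9.36e-14 to 0.292 over the left-out arrays) and the endothelial markers (1.66e-07; up to 0.898) reversed direction against WT Scl-. Counted once per list, comparison and setting, 49 results lost the threshold, 42 gained it, 2 reversed direction and 627 stayed. Counted once per named gene, comparison and setting, 10 results lost it, 136 gained it and 2947 stayed. All 10 losses were of Cdkn1c, the only named gene that passed over all genes as reported. Results that stayed include those that never passed. No setting moved the median of all genes by over 0.1 log units.

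The labels link replicates of different groups only by a number. Same-numbered deviations correlated at 0.25 for each pair of groups, across genes, a hint from the data that these arrays deviated in part together. The block leaves every difference as it was and changes only its spread. The replicate block gave 2 genes higher and 1 lower for SclKO against WT Scl+, and 4 more list results passed: Wnt and BMP genes in WT Scl+ against WT Scl- (adjusted p = 0.0178 and 0.0183), and paraxial and BMP genes in SclKO against WT Scl+ (0.0257 and 0.0183).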

Other observations

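The tests on WT Scl- replicate 2 and on chromosome 11 were chosen only after the results were seen, and so was the test of a second active Cdkn1c copy. The other tests on Cdkn1c were written before theirs. However, the readings of those on its imprinted domain and on other imprinted genes were changed after their values were seen. Wnt pathway genes did not pass as a group in the fit as reported (adjusted p = 0.0541, 0.17 and 0.68), yet single members differed over the list alone. In WT Scl+ against WT Scl-, the ligands Wnt5a and Wnt5b differed by -2.41 (SE 0.44) and -1.63 log units (SE 0.4), the receptor Fzd7 by -1.45 (SE 0.35), Lef1, a transcription factor of the pathway, by -1.18 (SE 0.33) and the inhibitor Dkk1 by -1.03 (SE 0.19). Lgr5, a receptor for R-spondins, went the other way, at 1.47 log units (SE 0.34). Wnt5b and Fzd7 differed by -1.02 and -0.92 without WT Scl+ replicate 2, and without WT Scl- replicate 1 Lgr5 differed by 0.95. In SclKO against WT Scl+, all 6 passed over the list alone in the opposite direction, and Lgr5 was at 4.7 ± 0.24 in SclKO, 7.5 ± 0.07 in WT Scl+ and 6.03 ± 0.74 in WT Scl- (mean ± SD, n = 2). Against WT Scl-, 0 of the 18 Wnt genes passed over the list alone. Without WT Scl+ replicate 2 the Wnt group passed in the first 2 comparisons (adjusted p = 0.00556 and 0.0476). With all arrays kept, it passed in WT Scl+ against WT Scl- with the replicate block (0.0178), the mean of all probe sets (0.0326), quantile normalisation (0.0309) and no filter on dim genes (0.0283).

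Arterial and Notch genes did not pass as a group (adjusted p = 0.894, 0.68 and 0.974), and members lay on both sides. In SclKO against WT Scl+, the chemokine receptor Cxcr4 was higher by 1.55 log units (SE 0.39; 0.94 without WT Scl+ replicate 2), Unc5b by 0.76 (SE 0.22) and Hey1 by 0.75 (SE 0.15), while Hey2 differed by -1.85 (SE 0.32) and Efnb2, an arterial ephrin, by -0.9 (SE 0.17), all 5 passing over the list alone. Among paraxial and somitic genes, which did not pass as a group (adjusted p = 0.0925, 0.0503 and 0.184), Mesp2 and Dll3 were higher in SclKO than in WT Scl+ by 1.79 (SE 0.34) and 1.26 log units (SE 0.15). Foxc2 was higher in WT Scl+ than in WT Scl- by 1.48 log units (SE 0.3; 0.88 with the dim WT Scl- values set to the limit). Of smooth muscle and mesenchymal genes (adjusted p = 0.211, 0.182 and 0.622), Twist1 was higher in SclKO than in WT Scl+ by 0.89 (SE 0.17) and than in WT Scl- by 0.84 log units (SE 0.17), and Pdgfra was higher than in WT Scl+ by 1.61 (SE 0.34). In the same 3 comparisons the adjusted p was 0.102, 0.0731 and 0.66 for BMP and TGF-beta genes, 0.0541, 0.0738 and 0.974 for cell cycle genes, and 0.438, 0.25 and 0.572 for dissociation and stress genes. It was 0.68, 0.221 and 0.181 for pluripotency genes, and 0.211, 0.199 and 0.474 for neural and surface ectoderm markers. Endoderm markers had an adjusted p = 0.0639 and 0.676 in the first 2 comparisons, hypoxia and glycolysis genes 0.26 and 0.305, imprinted genes 0.296 and 0.639, erythroid genes 0.66 in the third, macrophage markers 0.615, and cardiac contractile genes 0.66. Median, mean and test did not agree in sign for arterial and Notch genes (median 0.07, mean -0.05, test down) and pluripotency genes (0.01, 0.07, down) in the first comparison, and for arterial and Notch genes (0.03, 0.01, down), cardiac contractile genes (0.01, -0.05, down) and Wnt pathway genes (0.07, -0.04, down) in the third. Some of these lists passed when 1 array was left out. In WT Scl+ against WT Scl- they were paraxial and BMP genes without WT Scl- replicate 2 (adjusted p = 0.0278 and 0.0475), endoderm markers without WT Scl+ replicate 2 (0.00108), and endoderm, smooth muscle, cell cycle and hypoxia genes without WT Scl- replicate 1 (0.00974, 0.0383, 0.0423 and 0.0131). In SclKO against WT Scl+ they were paraxial genes without WT Scl+ replicate 2, WT Scl- replicate 1 or WT Scl- replicate 2 (0.033, 0.0149 and 0.0196) and BMP genes without WT Scl+ replicate 2 or SclKO replicate 2 (0.0499 and 0.0293). In SclKO against WT Scl- they were paraxial and pluripotency genes without WT Scl- replicate 1 (0.0202 and 0.0362) and macrophage markers without WT Scl- replicate 2 (0.0221). Some also passed with all arrays kept. In WT Scl+ against WT Scl-, paraxial, endoderm, BMP and imprinted genes did so with the mean of all probe sets (0.0469, 0.0238, 0.0482 and 0.0327), paraxial and BMP genes without a filter on dim genes (0.0153 and 0.0488), BMP genes with the replicate block (0.0183) and cell cycle genes with quantile normalisation (0.047). In SclKO against WT Scl+, paraxial and BMP genes did so with the replicate block (0.0257 and 0.0183), the mean of all probe sets (0.0232 and 0.0469) and no filter on dim genes (0.0474 for each), where smooth muscle genes passed too (0.0488), and paraxial genes with quantile normalisation (0.047). The list of Y-linked genes and Xist had 4 members tested, too few for a test, with a median difference of -0.04, 0 and 0.02 log units.

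WT Scl- replicate 2 lay nearer to WT Scl+ than replicate 1 did, by 1.45 log units for Tal1 and by a median of 1.68 over 32 blood and endothelial list genes at least 1 log unit higher in WT Scl+ than in SclKO, a choice that does not use the WT Scl- arrays. One factor for all genes between the 2 arrays could not be weighed, because RMA quantile-normalises and would have removed it (log medians 5.23 and 5.25). What the values show is that 14 streak genes moved the other way, by a median of -0.39 log units (quartiles -0.64 and -0.22). These were the streak genes at least 0.5 log units lower in WT Scl+ than in SclKO. Between the SclKO arrays the same genes differed by a median of 0.5 log units, and 25 of the 32 by under 0.5 times the WT Scl- difference. Over all 47 tested genes of the 2 lists the medians were 1.4 in WT Scl- and 0.39 in SclKO. However, the 32 genes were chosen for a low level in SclKO, where some, such as Myb, were dim on both arrays. A shift shared by the arrays numbered 2 might therefore show there only in part, and it stays open. WT Scl+ cells among the sorted cells of replicate 2 may contribute: a mixture would need a share of 37.9% by the median of these genes (quartiles 26.8% and 44.9%) and 48.4% by Tal1, with 33.5% by the 14 streak genes (26.9%, 40.8% and 39.3% if 1 log unit is 2.72-fold). The sort for cells without human CD4 was meant to keep such cells out, and the labels give no purity. The streak genes do not single out this array, since they differed by -1.03 log units between the WT Scl+ arrays, in the same direction, and by -0.11 between the SclKO arrays, and the blood and endothelial genes also rose between the WT Scl+ arrays (0.48). No biological explanation was tested, since the labels give nothing that sets the 2 WT Scl- arrays apart.

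Tested genes of chromosome 11 were lower in SclKO than in WT Scl- by a median of -0.154 log units, while the 18 other autosomes had medians between 0.012 and 0.06. The expression level of its genes is argued against as the cause: 10000 random lists of 1119 genes matched on mean expression had medians between 0.009 and 0.062. A few strain-variant probe sets are argued against too, since 79.5% of the genes lay below the median of the other autosomes. A copy number difference between the ES lines is a candidate explanation: in 5 consecutive segments of the chromosome the median relative to other autosomes lay between -0.21 and -0.16 log units, and both SclKO arrays showed it (-0.127 and -0.123, against 0.055 to 0.077 on the WT arrays). The relative level of 0.88 or 0.83 is nearer to 1 than the 0.67 that 2 copies against 3 in every cell would give. That gap does not weigh against a copy number difference, since measured ratios may be compressed towards 1 (spike-in slope 0.659 under the 2-fold reading). An effect of the knockout stays open, untested and confounded with the ES line.

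Cdkn1c was higher in SclKO than in WT Scl+ by 3.9 and than in WT Scl- by 3.95 log units, with Igf2 higher and Meg3 and Rian lower on the same arrays. A second active copy, as after loss of its imprint, would add no more than the level of an active first copy, 1 log unit at most. The smaller of the 2 differences was 3.9 (SE 0.2), or 2.97 with the dim WT values set to the limit for dim genes. This argues against a second copy as the whole rise, if the first was active in the WT cells. Cdkn1c was dim on all WT arrays, so these values do not show whether it was. A lost imprint over its chromosomal domain as a part of the rise stays open. Of other genes of that domain expressed from the maternal copy, Phlda2 was higher in SclKO by 2.65 against WT Scl+ and 1.02 against WT Scl-, while Slc22a18 (-0.05 and 0.09) and Ascl2 (-0.22 and -0.01, at a dim mean level of 4.53) moved little. Their median was 0.02 log units, which the rule written beforehand read as against a lost imprint. That reading was set aside after the values were seen, because Phlda2 rose and the others did not. Kcnq1 (-0.05 and -0.02), Cd81 (-0.23 and 0.07) and Tspan32 (-0.13 and 0.05), also of that region, moved little, and Tssc4 (0.25 and 0.41) and Nap1l4 (0.33 and 0.28) rose slightly. Kcnq1ot1, the non-coding RNA of the paternal copy, differed by -0.33 and -0.79 log units, and what this fall means for the imprint was not tested. A strain variant or cross-hybridisation at the probe set stays open, because 0 other probe sets read Cdkn1c alone. A wider difference of imprinted genes between the ES lines could contribute and cannot be told apart from other sources: the median absolute difference of the 20 other imprinted genes, 0.39 log units, lay at percentile 100 of 10000 matched random lists, but so did that between the WT groups of a single line (0.44 log units, percentile 100). The rule written beforehand used only the first of these percentiles and read it as pointing to a difference between the lines. An effect of the knockout itself is confounded with the ES line and stays open.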
